A study of Mus musculus with 24 samples.

How the data were processed

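Poly(A)-selected RNA of prefrontal cortex was sequenced from 24 C57BL mouse offspring, per the labels, 12 from dams given acetaminophen and 12 from control dams, with 6 females and 6 males in each arm. Per the series design text, treated dams received 150 mg/kg/day in palatable gelatin tablets from embryonic day 10 to postnatal day 21, and the sampled offspring were taken from their litters at birth. Sampling at birth is hard to square with dosing to postnatal day 21 and with high levels of Mbp and Pvalb in all 24 libraries, genes whose expression in mouse cortex rises after birth, so the age at sampling is unclear. Both genes were named after their values were seen. Which litter an animal came from is not given in the sources used here, so p-values measure the spread between these samples and take no account of shared litters. Groups follow the sex and treatment labels. Replicate numbers were given in accession order and only name a library. All control samples come before all treated ones in that order. A processing order that followed it could not be told apart from treatment.

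The deposited table holds 1 value per gene and library in a normalized signal unit, the read count of the gene divided by a size factor of the library. Per the series design text and the submitters' processing notes, the authors made it by filtering and trimming reads with fastp at default settings, mapping them with BWA-MEM to GRCm38 (mm10), assigning them to exons with featureCounts and normalizing them with DESeq2. Tool versions, the gene annotation and the strand setting are not given in the sources used here. BWA-MEM does not split reads across introns as a spliced aligner does, so genes with short exons may be undercounted. Without the strand setting it is not known whether reads of overlapping genes on opposite strands were told apart. Reads of near-identical gene copies may not have been told apart either.

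The table lists 27179 genes, of which 24061 have a value above 0 in at least 1 library. Gene IDs were named through a RefSeq gene table for 25275 genes and through GENCODE M21 for a further 18, and 1886 IDs stayed without a name. Within a library, 100.0% of values were whole multiples of what 1 read is worth, within 0.01 of a read, so whole reads were recovered for the count-based alternatives. Libraries held 40.4 to 74.3 M gene-assigned reads, with a mean of 58.9 ± 8.1 M (SD, n = 24). Within groups, the 60 pairs of libraries differed by a chi-square per gene of at least 20.7 (Pearson r across genes 0.9257 to 0.9892), so no library was treated as a repeat of another.

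The main test was limma (3.58.1, R 4.3.3) with an intensity trend on log2(normalized count + 1), on 17335 genes with a mean of at least 10, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that log2 scale, which understates changes of low genes. The treatment effect adjusted for sex and the sex effect adjusted for treatment came from a model with both factors (21 residual degrees of freedom). The effects in females, in males, their difference and the sex effect in controls came from a 4-group fit (20 residual degrees of freedom). The median standard error was 0.1 for the adjusted effect, 0.14 within a sex and 0.2 for the difference between sexes, giving 95% intervals of ± 0.21, ± 0.29 and ± 0.42.

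In advance, 53 gene lists with 1573 members were fixed, of which 1570 matched the table. They cover cell types of cortex and of neighbouring tissue, neuronal, metabolic, stress and immune pathways, and genes of acetaminophen handling. Lists were tested with camera at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry. Single members were also tested with adjustment over the list alone. Cross-tissue lists for heart, liver, lung, spleen with thymus and B cells, testis, kidney, pancreas, skeletal muscle, intestine, placenta, and stomach with skin keratin were written after heart and liver transcripts had been seen.

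Genes named per treatment comparison were the 10 largest changes in each direction past the threshold with a mean of at least 50, all that passed where fewer did, and, where fewer than 5 passed, up to 5 with the smallest unadjusted p. For each list past its threshold, its 3 members with the smallest unadjusted p could be named, and for other lists up to 3 members past the threshold over all genes. Always included were 5 sex-linked genes and 6 genes tied to acetaminophen action. For the sex comparisons, the 5 largest changes of each direction past the threshold with that mean were named. Predicted genes and genes without a name were counted, not named. Genes named outside this rule are marked as such.

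Alternatives set before the data were examined were pseudocounts of 0.5 and 5, no filter and a filter at 50, edgeR (4.0.16) and DESeq2 (1.42.0) on the recovered reads, quantile and TMM normalization, robust moderation, library weights, 1 surrogate variable (sva 3.50.0), other choices of samples and covariates, and each library left out in turn. After the data had been seen, 6 more were added: without the libraries labelled treated female 1 and treated female 4, without those low in heart transcripts (control female 1 to 4 and treated female 4), with olfactory bulb and striatal list scores as covariates, with the striatal score alone, with the erythroid score, and without treated female 6 and treated male 2. A list score is the mean z-score of its members. The gene set method EGSEA named in the series design text was not run here.

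The scripts were tested on simulated counts with 200 changed genes, so the shares recovered do not carry over to data in which few genes change. For a treatment change in both sexes, the adjusted test recovered 77.6% of genes changed 1.5-fold, 85.1% at 2-fold and 95.5% at 3-fold. The corresponding shares were 52.2%, 79.1% and 92.4% in females and 53.7%, 76.1% and 93.9% in males. For a change in males only, the interaction test recovered 32.8%, 55.2% and 80.3%. With nothing changed, 0 genes and 0 lists were called in each of these comparisons, but the simulated genes varied independently. With treatment reassigned within sex on the real values, camera at its preset correlation called a median of 17 lists in the adjusted effect, 18 in females, 14 in males and 17 in the interaction.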

Results

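The prefrontal cortex transcriptome was compared between offspring of dams given acetaminophen (150 mg/kg/day, an analgesic also known as paracetamol) and of control dams, in 4 groups of 6 libraries. Control females had 45.0 to 62.3 M gene-assigned reads, control males 46.7 to 61.5 M, treated females 44.2 to 74.3 M and treated males 40.4 to 71.6 M. Levels are normalized read counts, given as mean ± SD.

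The first comparison asked which genes differed with maternal acetaminophen once sex was accounted for. Rad54l, which encodes a motor protein of homologous recombination repair, rose in treated offspring, at 66.3 ± 11.4 (SD, n = 12) against 34.7 ± 9.02 (SD, n = 12) in controls. The change was 0.94 on the log2 scale (SE 0.14, limma adjusted p = 0.00963), and 12 of 12 treated libraries lay above the control median. As a list, Cell cycle genes, which serve DNA replication and mitosis, rose, while Immediate early genes, which neuronal activity induces, fell. Lists of microglia, endothelial and oligodendrocyte markers rose as well, and lists of GABA receptors, voltage-gated channels and synaptic vesicle proteins fell. These list calls hold with camera's preset correlation only, with adjusted p = 0.578 or higher with an estimated correlation.

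**Figure D1:**
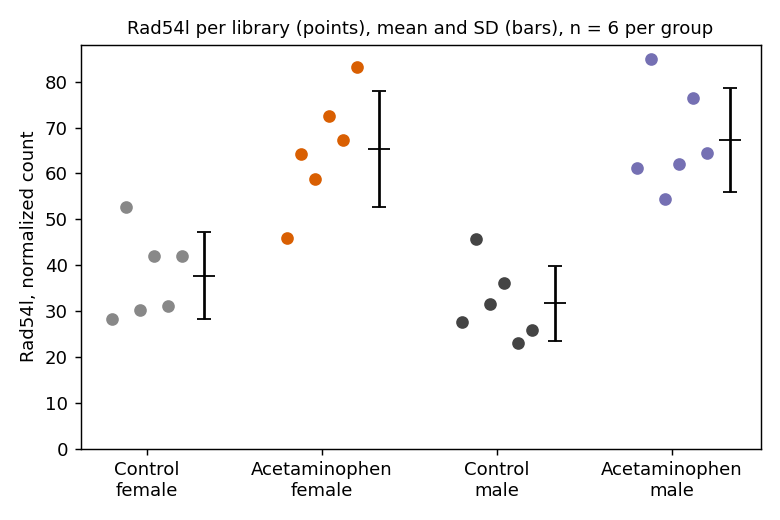
Normalized count of Rad54l (vertical axis, from 0) in each library of the 4 groups (points), with mean and SD beside them (n = 6 per group). Treated libraries lie between 46.0 and 85.0 and control libraries between 23.1 and 52.6.

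Rad54l lies on chromosome 4 (116094261 to 116123700, GRCm38) and was the 1 gene of 17335 past the limma threshold, with 0 lower. At an unadjusted p under 0.05 there were 593 higher and 521 lower genes, against 867 expected by chance. With edgeR 1 gene was called (Rad54l, adjusted p = 0.0211) and with DESeq2 11, of which 10 were higher. The end of Rad54l overlaps Lrrc41, named here after its values were seen, whose mean was 2770. Lrrc41 itself differed by -0.05 (SE 0.06, limma adjusted p = 0.881). As the strand setting is not given, it is not known whether reads in the overlap were told apart. The Rad54l call was lost after quantile normalization (0.81, limma adjusted p = 0.0604), among the 19 libraries of like heart transcript level (0.99, SE 0.16, limma adjusted p = 0.085) and without treated female 6 and treated male 2 (0.87, SE 0.15, limma adjusted p = 0.0905), the treated libraries with the highest erythroid scores (1.83 and 0.97). Treated female 6 and treated male 2 also held the most Rad54l (83.2 and 85.0).

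Of the genes that did not pass, those with the smallest p and higher levels in treated offspring were Plbd1, Derl3, Pax6os1, H4c8 and Myc. Plbd1, of the phospholipase B domain family, stood at 97.5 ± 31.9 (SD, n = 12) against 53.5 ± 17.1 (SD, n = 12). Derl3, a component of degradation at the endoplasmic reticulum, stood at 80.0 ± 16.5 against 53.2 ± 7.02, with limma adjusted p = 0.214 for both genes. The transcription factor Myc stood at 437 ± 117 against 306 ± 54.2 (limma adjusted p = 0.298). H4c8, a histone H4 gene that shares sequence with its copies, differed by 0.75 and Pax6os1, which runs antisense to Pax6, by 0.65. On the lower side, the potassium channel gene Kcnh5 stood at 983 ± 277 against 1550 ± 506 and the cadherin gene Cdh12 at 828 ± 174 against 1130 ± 217, each with limma adjusted p = 0.527. Ankrd34c differed by -0.59, Slc25a35 by -0.28 and Lrp12 by -0.20, with limma adjusted p = 0.533. DESeq2 called Plbd1, Derl3, Pax6os1, H4c8 and Myc, with adjusted p from 0.0143 to 0.0215.

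Among genes tied to acetaminophen action, the cyclooxygenase genes Ptgs1 (0.11, limma adjusted p = 0.835) and Ptgs2 (-0.31, limma adjusted p = 0.811) did not pass, and Ptgs2 stood at -0.18 without treated female 4. The cannabinoid receptor gene Cnr1 (0.01, limma adjusted p = 0.994) and Faah (-0.13, limma adjusted p = 0.825), which encodes a hydrolase of fatty acid amides, did not pass either. With 1 library left out, Cnr1 ranged from -0.04 (without control male 3) to 0.07 (without treated female 4), and Faah was -0.07 without treated female 4. Trpv1, at 5.24 ± 2.74 against 7.84 ± 7.25, lay under the filter. Cyp2e1, which oxidizes acetaminophen in liver, averaged 119 ± 378 in treated libraries. The library labelled treated female 4 held 1320 while the other 23 held 0 to 31.0, and only that library lifted the mean past the filter. The log2 change of Cyp2e1 was 1.41, or 0.77 without that library, and 1.17 in males. It did not pass, and the other values lie near the floor.

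Of 53 lists, 27 passed with camera, 16 higher and 11 lower. An estimated correlation gave 0 (smallest adjusted p = 0.578) and fry 0 (smallest adjusted p = 0.404), each with 2 lists at an unadjusted p under 0.05. When treatment was reassigned within sex, 10 of 100 splits, the real one included, gave as many lists (median of the others 17). Of the 43 Cell cycle genes 39 were positive, with a median of 0.26 (camera adjusted p = 7.25e-18, adjusted p = 0.578 with an estimated correlation). Over all genes 0 of them were called by limma, and 14 were higher when adjusted over the list alone. Among these, the mitotic kinase genes Aurkb (76.3 ± 26.0 against 38.2 ± 20.0) and Plk1 (78.6 ± 26.0 against 47.7 ± 15.5) differed by 1.08 and 0.70, and the replication helicase gene Mcm3 (513 ± 93.8 against 396 ± 66.0) by 0.37. Immediate early genes were negative in 25 of 32, with a median of -0.22 (camera adjusted p = 2.59e-06, adjusted p = 0.578 with an estimated correlation). Fos stood at 833 ± 502 against 1240 ± 415, and Dusp6 and Klf10 differed by -0.39 and -0.41, with limma adjusted p = 0.773 for these 3 genes.

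Microglia and macrophage genes were positive in 28 of 30 (median 0.15, camera adjusted p = 5.02e-06, adjusted p = 0.578 with an estimated correlation), with Cd68 at 666 ± 116 against 547 ± 113 and Fcer1g at 499 ± 134 against 389 ± 67.6. The microglia median was 0.09 without the libraries labelled treated female 1 and 4 (camera adjusted p = 0.00622) and 0.07 among the 19 libraries of like heart transcript level, where the call was lost (camera adjusted p = 0.0745). Interferon response genes were positive in 32 of 40 (median 0.15, camera adjusted p = 0.000451, adjusted p = 0.578 with an estimated correlation), including Oas2 (0.51) and Usp18 (0.39). Cytosolic ribosomal protein genes were positive in 71 of 78 (median 0.09, camera adjusted p = 0.000206, adjusted p = 0.712 with an estimated correlation). Oligodendrocyte genes were positive in 25 of 26 (median 0.19, camera adjusted p = 0.000451, adjusted p = 0.578 with an estimated correlation), with Cspg4 at 0.19. GABA receptor genes were negative in 17 of 20 (median -0.11, camera adjusted p = 0.000709, adjusted p = 0.578 with an estimated correlation), with Gabra5 at -0.28. Endothelial genes were positive in 26 of 30 (median 0.10, camera adjusted p = 0.000451) and voltage-gated channel genes negative in 24 of 29 (median -0.08, camera adjusted p = 0.00147), with adjusted p = 0.578 with an estimated correlation for both. Both calls were lost without the libraries labelled treated female 1 and 4 (medians 0.06 and -0.04, camera adjusted p = 0.148 and 0.111) and at like heart transcript level (0.06 and -0.04, camera adjusted p = 0.146 and 0.312). Synaptic vesicle genes were negative in 28 of 34 (median -0.09, camera adjusted p = 0.00147, adjusted p = 0.578 with an estimated correlation), with Snap25 at -0.16, and the call was lost with library weights (-0.04) and 1 surrogate variable (-0.03). Adjusted over the list alone, Gstp2 of acetaminophen conjugation (0.52), Nfkb2 (0.33), the nuclear RNA Neat1 (0.42), H4c8 and 1 gene of the thyroid hormone list were also higher, which with Cell cycle made 19 members higher and 0 lower, against 0 over all genes with limma.

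Lists of neighbouring tissue passed too, but their markers were high in single libraries. The striatal gene Drd1, named here after its values were seen, stood at 3900 in control female 4 and 4890 in treated female 5. Omp peaked at 2200 in control male 2 and, among treated libraries, at 282 in treated male 5. Striatal neuron genes were positive in 21 of 22 (median 0.33, camera adjusted p = 0.00552, adjusted p = 0.709 with an estimated correlation), with Six3 at 459 ± 651 against 219 ± 395, and the call was lost without treated female 5 (0.18) or treated male 6 (0.15). Olfactory bulb genes were negative in 10 of 13 (median -0.56, camera adjusted p = 0.0064, adjusted p = 0.578 with an estimated correlation), with Omp at 58.2 ± 89.2 against 460 ± 720. With both scores as covariates, Cell cycle kept a median of 0.25 (camera adjusted p = 5.54e-12) while the median of the oligodendrocyte list was 0.04 (camera adjusted p = 0.0649). Without the libraries labelled treated female 1 and 4, the median of the ribosomal list was 0 and that of the interferon list 0.07 (camera adjusted p = 0.922 and 0.382), and at like heart transcript level -0.02 and -0.04 (camera adjusted p = 0.423 and 0.568).

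**Figure D2:**
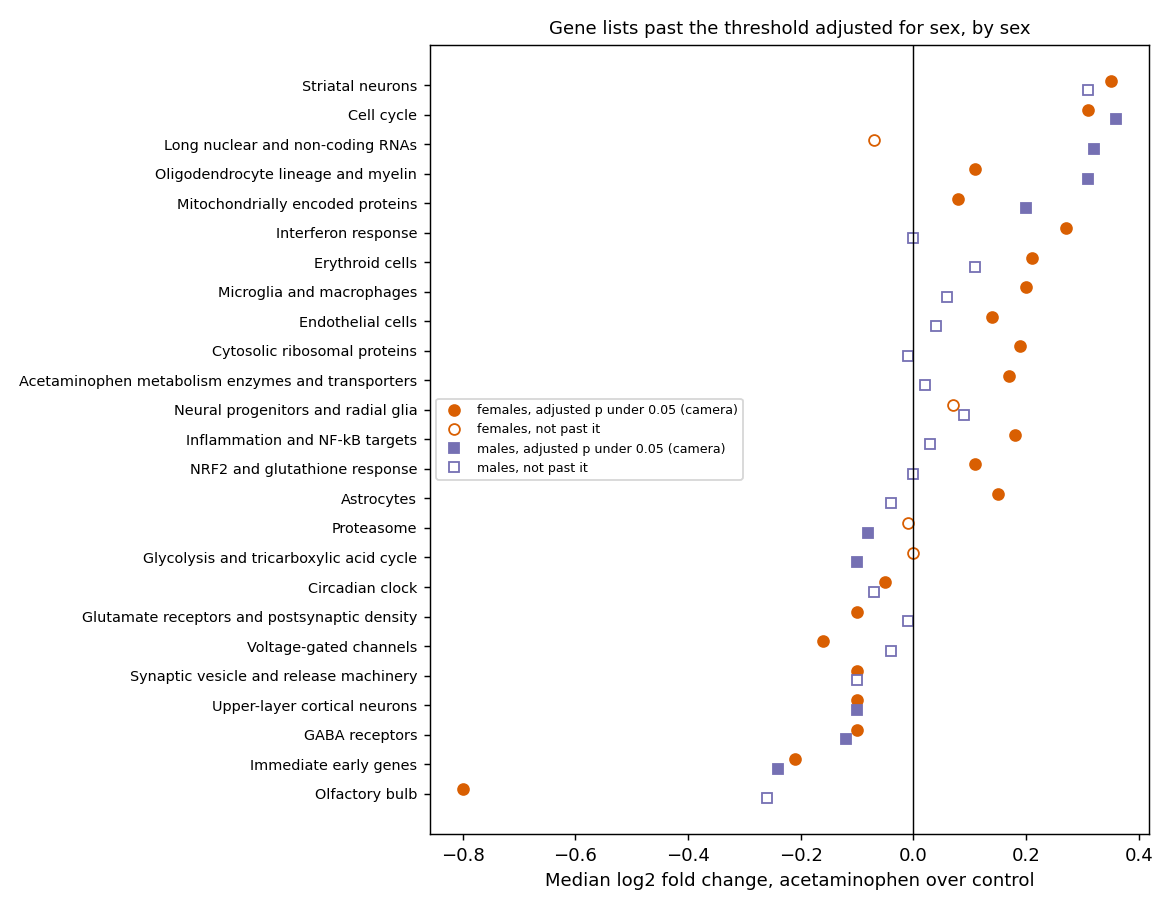
Median log2 fold change (horizontal axis) in females (circles) and males (squares) of the lists past the threshold in the comparison adjusted for sex, sex-linked lists left out. Filled symbols passed camera at its preset correlation in that sex, such as Cell cycle at 0.31 and 0.36, and open symbols did not.

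In females, no single gene passed the threshold. Cell cycle genes rose as a list, as did cytosolic ribosomal protein, microglia and interferon response genes, and autism-associated genes fell, each with adjusted p = 0.498 with an estimated correlation. Lists of neighbouring tissue passed as well, namely choroid plexus (median 0.45, camera adjusted p = 0.003), olfactory bulb (-0.80, camera adjusted p = 0.00259) and striatal genes (0.35, camera adjusted p = 0.023). With an estimated correlation their adjusted p was 0.501, 0.498 and 0.663. The library labelled treated female 1 had sex-linked transcripts at male levels, and the one labelled treated female 4 held 81400 normalized counts of liver genes against 80.7 to 410 in the other libraries. Without both, Cell cycle kept a median of 0.35 against 0.31 with them. The ribosomal list went from a median of 0.19 to 0.01, the interferon list from 0.27 to 0.02 and the autism-associated list from -0.13 to 0.00.

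With limma 0 genes were called in females, with 670 at an unadjusted p under 0.05, and edgeR called 0 and DESeq2 1. Rad54l stood at 65.3 ± 12.6 (SD, n = 6) against 37.7 ± 9.48 (SD, n = 6; limma adjusted p = 0.923). The other genes with the smallest p, all with limma adjusted p = 0.923, were higher for Flnc of the filamin family (565 ± 75.6 against 390 ± 85.7), the nucleoside transporter gene Slc28a2 (1.35), H4c8 (0.86) and Arhgap45 (0.52). They were lower for Mybpc1 (188 ± 82.6 against 350 ± 52.3, a log2 change of -1.07, or -0.71 without treated female 4), Fam135a (-0.37), Polr3f of RNA polymerase III (-0.23), Cfap69 (-0.58) and Adamts12 (-0.63). The self-test recovered 79.1% of simulated 2-fold changes in this comparison, with genes that varied independently. That share does not carry over to data in which few genes change. It therefore does not tell how many real changes of that size were missed. Leaving out the library labelled treated female 4 gave 2 genes, Ckmt2 and Fabp4, named here after their values were seen, each with limma adjusted p = 0.0482. Both were lowest in that library (0.732 and 18.3), and in control female 1 to 4, which were low in heart transcripts, Ckmt2 stood at 506 to 616 and Fabp4 at 203 to 236.

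Of 53 lists 33 passed with camera in females, 22 higher and 11 lower. An estimated correlation gave 0 (smallest adjusted p = 0.498) and fry 0 (smallest adjusted p = 0.483), each with 2 lists at an unadjusted p under 0.05. Other splits, with treatment reassigned within sex, gave a median of 18 lists and at most 32. Cell cycle genes were positive in 38 of 43 (median 0.31, camera adjusted p = 9.87e-09, adjusted p = 0.498 with an estimated correlation), with Cdk1 at 127 ± 32.6 against 78.2 ± 25.8 and Mcm2 at 493 ± 107 against 393 ± 36.3 (a log2 change of 0.31, or 0.20 without treated female 6). Erythroid genes rose as a list too, with 16 of 18 positive (median 0.21, camera adjusted p = 0.00948, adjusted p = 0.498 with an estimated correlation). Treated female 6 had the highest score, a mean z-score over members, in both lists (1.62 for Cell cycle and 1.83 for Erythroid), and without it and treated male 2, next in both, the female medians were 0.18 (camera adjusted p = 0.00158) and 0 (camera adjusted p = 0.563). Ribosomal genes were positive in 72 of 78 (camera adjusted p = 1.43e-09, adjusted p = 0.498 with an estimated correlation), with Rpl11 at 0.42. Microglia genes were positive in 29 of 30 (median 0.20, camera adjusted p = 1.08e-07, adjusted p = 0.498 with an estimated correlation) and stood at a median of 0.12 without the libraries labelled treated female 1 and 4 (camera adjusted p = 0.00297) and of 0.09 at like heart transcript level, where the call was lost (camera adjusted p = 0.182). Interferon genes were positive in 35 of 40 (camera adjusted p = 9.95e-07, adjusted p = 0.498 with an estimated correlation), with Tap1 at 0.39. Autism-associated genes were negative in 51 of 56 (camera adjusted p = 1.11e-05, adjusted p = 0.498 with an estimated correlation), with the ubiquitin ligase gene Ube3a at -0.24, or -0.12 without treated female 4. NRF2 and glutathione genes were positive in 31 of 37 (median 0.11, camera adjusted p = 4.1e-05, adjusted p = 0.498 with an estimated correlation), with the quinone reductase gene Nqo1 at 391 ± 84.3 against 279 ± 27.9. Inflammation genes were positive in 25 of 29 (median 0.18, camera adjusted p = 0.000197, adjusted p = 0.498 with an estimated correlation), among them complement C3, at 9550 in the library labelled treated female 4 and at 162 to 406 in the other treated females. Adjusted over the list alone, H4c8 and H4c9 of the histone list were higher, against 0 members over all genes with limma. The list count was 12 without the libraries labelled treated female 1 and 4, and 17 without treated female 4 alone. Among the libraries of like heart transcript level, the ribosomal median was -0.08 (camera adjusted p = 0.0516) and the autism-associated median 0.05 (camera adjusted p = 0.354). Interferon genes passed there in the opposite direction (-0.15, camera adjusted p = 0.0108), as did complex I genes (-0.14, camera adjusted p = 0.000776) and mitochondrial ribosomal genes (-0.06, camera adjusted p = 0.00679). Only control female 5 and 6 remain as female controls there, and control female 5 stood apart, with scores of 2.07 for complex I, 1.66 for mitochondrial ribosomal, 1.38 for ribosomal and 0.63 for interferon genes, against -0.53, -0.54, -0.24 and 0.17 in control female 6. The NRF2 call was lost in both settings (medians 0.02 and 0.03, camera adjusted p = 0.348 and 0.744) and the inflammation call at like heart transcript level (0.03, camera adjusted p = 0.613).

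In males, Cell cycle genes rose as a list, and glycolysis with the tricarboxylic acid cycle, Immediate early genes and the unfolded protein response fell, with adjusted p of 0.708 to 0.945 with an estimated correlation. No single gene passed with limma. Rad54l stood at 67.3 ± 11.3 (SD, n = 6) against 31.7 ± 8.20 (SD, n = 6), a log2 change of 1.08 (SE 0.20, limma adjusted p = 0.23). With 0 genes called by limma there were 662 at an unadjusted p under 0.05, and edgeR called 0 and DESeq2 1, Rad54l (adjusted p = 0.00759).

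The other male genes with the smallest p, all with limma adjusted p = 0.988, were higher for Myc (517 ± 101 against 323 ± 71.3), the actin-binding Lsp1 (483 ± 67.5 against 316 ± 58.0), the folate enzyme gene Fpgs (432 ± 28.2 against 340 ± 30.7) and the Hedgehog acyltransferase gene Hhat (70.3 ± 9.08 against 41.0 ± 14.1). They were lower for Lrp12 (-0.28), Pcdhb5 of the clustered protocadherins (-0.40), Acad9 (-0.21), the co-chaperone gene Bag5 (-0.24) and Mei1 (-0.65). Of 53 lists 14 passed with camera, 5 higher and 9 lower. An estimated correlation gave 0 (smallest adjusted p = 0.708) and fry 0 (smallest adjusted p = 0.683), each with 3 lists at an unadjusted p under 0.05. With treatment reassigned within sex, 58 of 100 splits, the real one included, gave as many lists. The median of the others was 14, so the count does not exceed chance. Cell cycle genes were positive in 40 of 43 (median 0.36, camera adjusted p = 5.94e-14, adjusted p = 0.708 with an estimated correlation), with Aurkb at 82.2 ± 23.5 against 31.8 ± 16.5 and Mcm7 at 351 ± 57.1 against 253 ± 46.7. Aurkb was the 1 member called higher when adjusted over the list alone, against 0 over all genes with limma. Glycolysis and tricarboxylic acid cycle genes were negative in 33 of 34 (median -0.10, camera adjusted p = 6.34e-08, adjusted p = 0.886 with an estimated correlation), with Dlst at -0.14 and the phosphofructokinase gene Pfkm at -0.24, or -0.11 without treated male 1. Immediate early genes were negative in 27 of 32 (median -0.24, camera adjusted p = 2.37e-05, adjusted p = 0.945 with an estimated correlation), with Dusp1 at 911 ± 173 against 1550 ± 511 and Junb at 2000 ± 362 against 3060 ± 703. Unfolded protein response genes were negative in 29 of 39 (median -0.07, camera adjusted p = 0.00253, adjusted p = 0.708 with an estimated correlation), with the chaperone gene Hspa5 at -0.17. Long nuclear and non-coding RNAs were positive in 14 of 17 (median 0.32, camera adjusted p = 0.000718, adjusted p = 0.708 with an estimated correlation), with the imprinted Meg3 at 19400 ± 8630 against 9080 ± 5410.

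The interaction asked whether the effect of acetaminophen differed between the sexes, as the male minus the female effect. Autism-associated and deep-layer cortical neuron genes were higher on this scale, and cytosolic ribosomal protein, glycolysis, oxidative phosphorylation and unfolded protein response genes lower, with adjusted p of 0.46 to 0.779 with an estimated correlation. No single gene passed. Without the libraries labelled treated female 1 and 4, the ribosomal median went from -0.19 to -0.03 and the autism-associated median from 0.18 to 0.06, and the glycolysis median from -0.11 to -0.07 (camera adjusted p = 0.00275). Among the 19 libraries of like heart transcript level these calls were lost, at medians of 0.05, 0 and -0.01 (camera adjusted p = 0.0941, 0.931 and 0.931), as were those of the unfolded protein response (-0.03), complex I (0.06), complexes II to V (0.03) and deep-layer genes (0.02).

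For the interaction, limma called 0 genes, with 291 at an unadjusted p under 0.05, and edgeR and DESeq2 called 0. The smallest p, all with limma adjusted p of 1, were found for Ap4e1 (0.65) and Tepsin (0.41) of the AP-4 sorting complex, Ddx55 (0.36), Zfp874b (0.64) and Zfp963 (0.55) on the higher side. On the lower side they were found for Tfam, a packaging factor of mitochondrial DNA (-0.34), Lpo (-1.40), the peptide transporter gene Tap2 (-0.65), Pla2r1 (-1.02) and the nucleoporin gene Nup62 (-0.23). Of 53 lists 25 passed with camera, 6 higher and 19 lower. An estimated correlation gave 0 (smallest adjusted p = 0.46) and fry 0 (smallest adjusted p = 0.644), each with 1 list at an unadjusted p under 0.05. Reassigning treatment within sex gave as many lists in 15 of 100 splits, the real one included (median of the others 17). The list count was 9 without the libraries labelled treated female 1 and 4. Ribosomal genes were negative in 69 of 78 and autism-associated genes positive in 52 of 56 (camera adjusted p = 2.4e-06 and adjusted p = 0.779 with an estimated correlation for both), with Asxl3 at 0.77. Glycolysis genes were negative in 33 of 34 (camera adjusted p = 2.4e-06, adjusted p = 0.773 with an estimated correlation), with the lactate dehydrogenase gene Ldhb at -0.33. Unfolded protein response genes were negative in 34 of 39 (median -0.13, camera adjusted p = 5.53e-05, adjusted p = 0.46 with an estimated correlation), with Hspa5 at -0.20. Nuclear genes of oxidative phosphorylation were negative in 36 of 37 for complex I (camera adjusted p = 6.8e-05) and in 38 of 39 for complexes II to V (camera adjusted p = 6.99e-05), with adjusted p = 0.779 with an estimated correlation for both. Without the libraries labelled treated female 1 and 4 both calls were lost, at a median of -0.05 each (camera adjusted p = 0.358 and 0.497). Deep-layer genes were positive in 23 of 26 (median 0.30, camera adjusted p = 0.000144, adjusted p = 0.773 with an estimated correlation), with Nr4a2 at 1.56. Across 17335 genes, female and male effects correlated with Pearson r = 0.248 and Spearman rho = 0.168, with 55.7% of genes of like sign. Pearson r ranged from 0.139 to 0.329 with 1 library left out and from 0.109 to 0.319 over the alternatives set in advance. Genes are not independent replicates, and each sex had its own controls.

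The sex comparison checked the labels. Male libraries held more of the Y-linked Ddx3y (3980 ± 299 against 385 ± 985, SD, n = 12 each), Kdm5d, Uty and Eif2s3y, and less of Xist, the RNA of the inactive X (60.7 ± 21.7 against 4920 ± 3900), and of the escape gene Eif2s3x (2520 ± 204 against 3600 ± 403). In limma 8 genes passed, 5 higher and 3 lower in males, both over all libraries and in controls alone. In controls, Ddx3y stood at 3950 ± 310 (SD, n = 6) against 84.8 ± 60.4 (limma adjusted p = 1.06e-05) and Xist at 53.1 ± 18.8 against 5590 ± 3320 (limma adjusted p = 1.06e-05). The library labelled treated female 1 held 103 of Xist, where the other females held 1220 to 13100 and the males 31.4 to 93.0. Its Ddx3y was 3510, where males held 3410 to 4390 and the other females 26.3 to 167.

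**Figure D3:**
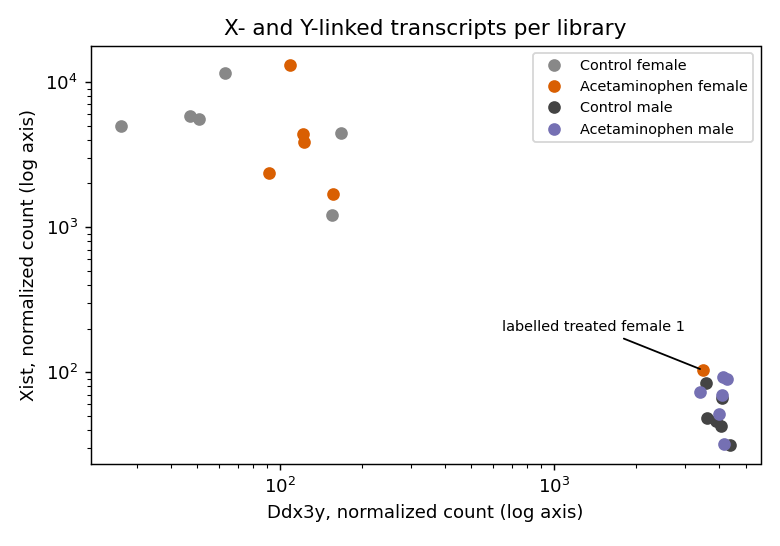
Normalized count of Ddx3y (horizontal axis, log) against Xist (vertical axis, log) in 24 libraries, colored by labelled group. The library labelled treated female 1 lies with the males, at 3510 and 103.

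Heart transcripts were high in 23 libraries, where the cardiac myosin gene Myh6 stood at 9040 to 22100, against 269 in the library labelled treated female 4. The sum over a 15-gene heart list was 28900 to 31800 in control female 1 to 4 and 46200 to 76000 in the other libraries except that one, at 818. It held 47800 counts of the albumin gene Alb, named like Myh6 after its values were seen, against 0 to 125 in the other 23.

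**Figure D4:**
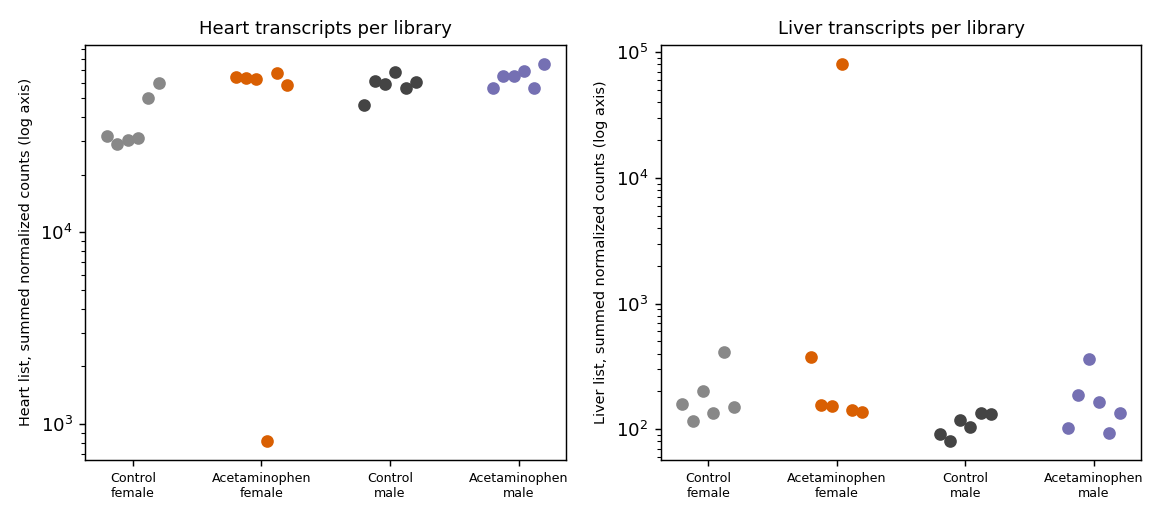
Summed normalized counts (vertical axes, log) of heart genes (left) and liver genes (right) in each library of the 4 groups (points). The library labelled treated female 4 is lowest for heart, at 818, and highest for liver, at 81400.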

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

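The rule of the outlier search and the list tests between sexes were set before the data were examined. Some items of the search, namely the heart and liver sums, Drd1 and Ttr, and the tests of explanations were chosen after the results had been seen. Of 368 groups of 6 libraries over 92 items, 45 had a highest or lowest library far from the others. Chance would give about 18 for normal and independent values. Counts such as those of Six3 are skewed and many items are related, so the excess over 18 is no measured departure from chance.

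In the library labelled treated female 1, the Y-linked genes Ddx3y (3510), Kdm5d (1020), Uty (869) and Eif2s3y (1480) stood at male levels, where the other treated females held 91.5 to 156, 13.4 to 44.3, 7.32 to 41.0 and 31.5 to 114. An exchange of sex labels with a male library of the set is argued against, as 0 male-labelled libraries had Xist above the lowest other female. A mixture of female and male tissue is argued against too, as Xist above the male mean was 0.965% of the median of the other females. A single wrong sex label, or an exchange with a sample outside the set, is consistent with the 5 sex-linked genes, which lay at most 1.61 SDs from the male mean. The label was kept, and no biological explanation was tested.

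The library labelled treated female 4 had the lowest heart sum, 818 against 58500 to 67700 in the other treated females, and the highest liver sum, 81400 against 136 to 376. The median heart sum of the other 23 libraries was 73.3 times that of this one, a gap in 1 library that does not decide whether the cortex itself expressed these genes. Control female 1 to 4, set apart by their heart sums, also held fewer Y-linked transcripts than 6 other female libraries (sums of 107 and 294, exact permutation p = 0.00476, the smallest that 210 splits can give), but treated female 4, lowest in heart transcripts, held 148, above their 78.0 to 123. Reads of other libraries assigned to these therefore cannot be told apart from heart tissue in the dissected samples or expression by the cortex, since the heart sum of the 4 libraries varied by 4.19% (CV) and no bound is known for separate dissections. No biological explanation was tested.

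Of the same library, C3 stood at 9550 (others 162 to 406), Cyp2e1 at 1320 (0 to 23.7), Slc28a2 at 274 (41.8 to 70.7), Cdh12 at 388 (760 to 970) and Ube3a at 1980 (2970 to 3490). Among other treated females, Plbd1 was 150 (72.5 to 82.7), Mcm2 707 (415 to 477) and Pcdhb5 228 (265 to 286) in replicate 6. Dusp6 was 5620 (1500 to 3040) in replicate 3, and Meg3 was 29900 (3990 to 11100) and Xist 13100 (103 to 4370) in replicate 5.

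Among control females, replicate 5 had 45.0 M reads (58.6 to 62.3 M), Cyp2e1 at 31.0 (0 to 5.87), Slc28a2 at 59.3 (17.6 to 32.0) and a liver sum of 410 (117 to 203). Mcm2 was 321 (397 to 420) in replicate 2, Kdm5d 51.9 (8.21 to 20.2) in replicate 6 and Pfkm 32000 (35600 to 36900) in replicate 1. Among control males, replicate 4 had 46.7 M reads (58.2 to 61.5 M), Cd68 at 832 (436 to 538), Nfkb2 at 578 (448 to 496), Tap1 at 486 (270 to 330), Acad9 at 2550 (3020 to 3160), Six3 at 762 (2.01 to 87.4) and the striatal gene Drd1 at 2680 (347 to 574). Replicate 3 had Cdk1 at 144 (74.5 to 95.9), Pcdhb5 at 385 (245 to 287), Mei1 at 207 (127 to 153) and the choroid plexus gene Ttr at 74800 (298 to 707), and in replicate 5 Slc25a35 was 172 (220 to 237).

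Among treated males, replicate 1 had Dusp6 at 3210 (2310 to 2620) and Pfkm at 20100 (33100 to 35200). Replicate 3 had H4c9 at 155 (79.8 to 90.0), Ttr at 26900 (129 to 1560) and a liver sum of 365 (92.7 to 188). Replicate 6 had Nr4a2 at 2630 (710 to 1240), Drd1 at 4020 (338 to 1410) and Eif2s3x at 2000 (2390 to 2570), and in replicate 4 Ddx3y was 3410 (4000 to 4280). Drd1 and Ttr were named after their values had been seen.

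The effect of treatment differed between the sexes (male minus female) for 25 lists by camera at its preset correlation, and for 0 with an estimated correlation, with adjusted p of 0.46 for the unfolded protein response and 0.773 or 0.779 for the rest. Medians were positive for autism-associated (0.18), deep-layer (0.30), long non-coding RNA (0.29), axon guidance (0.11), X-escape (0.14) and voltage-gated channel (0.14) lists. They were negative for cytosolic ribosomal (-0.19), mitochondrial ribosomal (-0.11), glycolysis (-0.11), unfolded protein (-0.13), oxidative phosphorylation complex I (-0.15) and complexes II to V (-0.14), NRF2 (-0.11), proteasome (-0.06), histone (-0.13), acetaminophen metabolism (-0.12) and prostaglandin (-0.12) lists. Further negative medians were those of interferon (-0.25), inflammation (-0.21), microglia (-0.19), astrocyte (-0.15), endothelial (-0.14), meningeal (-0.21), choroid plexus (-0.64) and Y-linked (-1.54) lists, the last with a treated female library at male levels. The number of lists was 9 without treated female 1 and 4, and 6 among the libraries of like heart transcript level.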

How the results depend on the processing

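Alternatives were planned before the data were examined, except those on treated female 1 and 4, treated female 6 with treated male 2, like heart transcript level and list scores, which were chosen after the data had been seen. Over 13 alternatives set in advance the Rad54l change was 0.81 to 0.95 (limma, edgeR or DESeq2 adjusted p from 6.14e-06 to 0.0604), and with each of 24 libraries left out 0.89 to 0.99 (limma adjusted p from 0.00323 to 0.0311). Among the genes named by the rule, list members aside, called ones reversed 0 times, 9 results lost their call and 8 gained one. Uncalled genes that changed sign, such as Cnr1, were not counted, nor were calls of other genes, such as Ckmt2, Fabp4 and Kynu. Called lists reversed, meaning that camera's direction against the other genes turned, 36 times and lost their call 438 times, and with 1 library left out reversed 1 time and lost it 229 times. Of these, 5 passed in the opposite direction, namely oligodendrocyte in females with 1 surrogate variable and, at like heart transcript level, complex I, mitochondrial ribosomal and interferon in females and interferon in the interaction. In 6 of the 37 the median kept its sign or was 0. None came with quantile normalization, TMM, edgeR or DESeq2. The cause was not tested unless given. Libraries held at least 40.4 M reads. Genes with a mean under 10 were left out of the main test and fitted only with no filter and with DESeq2, which thus began from more genes. Changes of such genes stay largely open.

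For the effect adjusted for sex, DESeq2 called 11 genes, library weights 4 and quantile normalization with limma 0 (895 at an unadjusted p under 0.05). DESeq2 called 1 gene in females, 1 in males and 4 in the sex effect in controls. Lists numbered 0 with an estimated correlation in the adjusted effect, 0 in females, 0 in males and 0 in the interaction, and likewise 0, 0, 0 and 0 with fry. Library weights gave 21 lists in females and 1 surrogate variable 17 in the adjusted effect.

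Without treated female 6 and treated male 2, limma called 0 genes in the adjusted effect (967 at an unadjusted p under 0.05). Without treated female 1 and 4, lists numbered 12 in females and 9 in the interaction. Among the libraries of like heart transcript level, which are fewer, limma called 0 genes in the adjusted effect (1568 at an unadjusted p under 0.05), 1 in females (Kynu, named after its values were seen) and 0 in the sex effect in controls (344 at an unadjusted p under 0.05), with 15 lists in females and 6 in the interaction. With 1 library left out, genes in females numbered 0 to 2 and lists in females 17 to 34, with 2 and 17 without treated female 4. The oligodendrocyte median in females ranged from -0.06, without treated female 4, to 0.24.

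The reversed list with library weights was oligodendrocyte in females (median -0.05). With 1 surrogate variable they were striatal (-0.12) and oligodendrocyte (-0.05) in the adjusted effect and striatal (-0.21) and oligodendrocyte (-0.21) in females. With both scores as covariates they were striatal (-0.02) and olfactory bulb (0.02) in the adjusted effect and striatal (-0.02) in females, with the striatal score alone striatal in the adjusted effect (-0.05), and with the erythroid score erythroid in the adjusted effect (0.01) and in females (-0.06), as these covariates remove the list itself. In 8 further cases the median changed sign while camera's direction did not turn and the call was lost. These were oligodendrocyte in females with both scores (-0.03) and the striatal score (-0.01), meningeal in females with library weights (-0.03), astrocyte (-0.01) and X-escape (0.01) in the adjusted effect without treated female 1 and 4, and, in females at like heart transcript level, Immediate early (0.03), glutamate receptor (0.02) and prostaglandin (-0.01). With 1 library left out this held for meningeal genes in females without treated female 3 (-0.05).

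Without treated female 1 and 4, reversed lists had medians of 0 (ribosomal, adjusted), 0.01 (ribosomal, females), -0.05 (oxidative phosphorylation complex I, females), -0.03 (mitochondrial ribosomal, females), -0.03 (ribosomal, interaction) and 0.02 (voltage-gated, interaction). At like heart transcript level they were -0.02 for ribosomal and -0.04 for interferon in the adjusted effect. In females they were -0.14 for complex I, -0.08 for ribosomal, -0.06 for mitochondrial ribosomal, -0.01 for unfolded protein, -0.15 for interferon, 0.13 for deep-layer, 0.05 for autism-associated and 0.07 for circadian lists. In the interaction they were 0.06 for complex I, 0.03 for complexes II to V, 0.05 for ribosomal, 0.01 for mitochondrial ribosomal, 0.06 for proteasome, 0.13 for interferon, -0.03 for voltage-gated, -0.06 for axon guidance and 0 for autism-associated lists.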

Other observations

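The tests of explanations and the cross-tissue lists in this part were chosen after the results had been seen, and the splits were read with the results known. Maturity markers, named after their values were seen, were high in all 24 libraries: the myelin gene Mbp at 43700 to 341000, the kinase gene Camk2a at 142000 to 303000 and the parvalbumin gene Pvalb at 2030 to 7320. The embryonic globin gene Hbb-y stood at 0 to 11.6 and Hbb-bh1 at 0. These levels go against sampling at birth, and the age of the animals is unclear. Mitochondrially encoded genes rose as a list in males (11 of 13 positive, median 0.20, camera adjusted p = 0.000193, adjusted p = 0.961 with an estimated correlation), with mt-Nd6 at 48900 ± 9880 (SD, n = 6) against 39100 ± 6670 (limma adjusted p = 0.988). Upper-layer cortical neuron genes fell in both sexes as a list, with 17 of 19 negative in each (camera adjusted p = 0.0171 in females and 0.0279 in males, with adjusted p = 0.498 and 0.961 with an estimated correlation). The female call was lost without treated female 1 and 4 (median -0.03, camera adjusted p = 0.444), with treated female 4 alone left out (-0.03), with library weights (-0.10), with both scores (-0.09) and at like heart transcript level (-0.10, camera adjusted p = 0.63). The male call was lost without control male 1 (-0.10) or 3 (-0.08) or treated male 2 (-0.06) or 3 (-0.10), and in both sexes with quantile normalization (-0.11 and -0.08) and 1 surrogate variable (-0.06 and -0.08).

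Other tissues gave these sums in the library labelled treated female 4, with the median of 22 others (without treated female 1) after it: heart 818 and 59700, liver 81400 and 135, lung 560 and 658, spleen with thymus and B cells 9600 and 2490, testis 423 and 486, kidney 2080 and 1670, pancreas 354 and 305. Skeletal muscle gave 5040 and 4770, intestine 323 and 322, placenta 2.2 and 0, and stomach with skin keratin 3430 and 1590. All 19 genes of the liver list were highest there, as were the B cell genes Jchain (3180) and Igkc (3240), named after their values were seen. This library lay at 113.1 on the first principal component (22.4% of variance), with the others from -33.6 to 35.0.

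Higher Rad54l in treated offspring stood at 0.94 with olfactory bulb and striatal scores as covariates and at 0.99 without treated female 1 and 4, which argues against either as its whole cause. A constant share of Lrrc41 reads is argued against by the Lrrc41 change of -0.05, while a change in read-through from Lrrc41 stays open. Among libraries of like heart transcript level the change was 0.99 (SE 0.16, against 0.94 and SE 0.14 before), and without treated female 6 and treated male 2 it was 0.87 (SE 0.15). The call was lost both times, while it held without treated female 1 and 4 (limma adjusted p = 0.00725). Treated female 6 and treated male 2 were highest in erythroid score among treated libraries and also highest in Rad54l of all 24 (83.2 and 85.0). For the Cell cycle list, the median was 0.25 with both scores, 0.33 without treated female 1 and 4 and 0.26 with the erythroid score, against 0.26. Rad54l stood at 0.93 with the erythroid score (limma adjusted p = 0.0305). The values with the erythroid score argue against erythroid cells as the whole cause. A part stays open, as the Erythroid list rose too (15 of 18 positive, median 0.15, camera adjusted p = 0.0159, adjusted p = 0.578 with an estimated correlation). Treated female 6 and treated male 2 had the highest Cell cycle (1.62 and 0.91) and Erythroid (1.83 and 0.97) scores, and the female Cell cycle median was lower without them. An effect of maternal acetaminophen may be a candidate explanation for Rad54l and the Cell cycle list. It is a hypothesis found and tested on the same data, and neither litter nor processing order was tested.

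Treatment was reassigned within sex, and sex within treatment, in 100 splits, the real one included. For genes in the adjusted effect, 1 of 100 gave as many as the real 1 (highest other 0). That 1 of 100 is the real split itself, the smallest share these splits can give. It argues against chance, but it rests on a count of 1 gene and takes no account of litter or processing order. For genes in females (real 0, highest other 1618), in males (real 0, highest other 0) and in the interaction (real 0, highest other 1098), 100 of 100 gave as many, which a real count of 0 fixes, so these splits say nothing of chance. The sex effect gave 1 of 100 (real 8, highest other 0) and in controls 1 (real 8, highest other 1), which argues against chance for both. For counts of lists, 10 of 100 were as large in the adjusted effect (real 27, highest other 30, median of the others 17), 58 in males (real 14, highest other 27, median 14) and 15 in the interaction (real 25, highest other 32, median 17), and chance cannot be excluded. In females it was 1, the real split itself (real 33, highest other 32, median of the others 18), a margin too small to settle the matter. The 33 include the Y-linked (camera adjusted p = 7.21e-05) and X-escape (camera adjusted p = 0.00298) lists, with a treated female library at male levels. The count also rests on treated female 4, since it was 17 without that library and 12 without treated female 1 and 4. The correlation of female and male effects was reached in 10 of 100 (real 0.248, highest other 0.341), and chance cannot be excluded. For the Cell cycle list, 1 of 100 had a p as small (18.86 as -log10 p, highest other 18.7, in a split with a negative median), but 4 of 100 had a median as large in the same direction, 5 in either, and 6 of 100 had some list with a p as small.

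The split with 1618 genes in females exchanged, among females, only the labels of control female 5 and treated female 5, with 721 higher and 897 lower, and points to a structure of the samples. An exchange of these 2 labels was not tested, and the labels were kept. Ribosomal (0.43), oxidative phosphorylation complex I (0.33) and complexes II to V (0.30) lists had positive medians in it, and the autism-associated list -0.30. Besides this split and the real one, 2 splits called any gene in females, with 1 gene at most.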
